A study of Homo sapiens with 6 samples.

How the data were processed

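RNA-seq of the multiple myeloma cell line JJN3 was compared between cells given DMSO, WNK463 for 2 h and WNK463 for 6 h, with 2 libraries per group. Per the file headers and the submitters' processing notes, the deposited counts are fragment counts per gene made with featureCounts 2.0.0 from paired reads aligned to hg38, without regard to strand, after trimming with Trimmomatic and alignment with STAR (versions not given). The table holds 60728 genes of GENCODE 34, 30725 of them with no count in any library. The record of ANK2, broken over 3 lines, was rejoined. Gene types and GC content came from GENCODE 29, since release 34 was not among the annotations held. Exon overlaps were computed from the exon coordinates in the deposited counts, and 1253 identifiers share a symbol with another.

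Counts were analysed in R 4.3.3 with edgeR 4.0.16 by quasi-likelihood tests, in a single fit of all 6 libraries with a mean per group, TMM factors (0.977 to 1.025) and the filterByExpr filter, which left 15548 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The common dispersion was 0.00597, a biological coefficient of variation of 7.72%. The comparisons were 2 h with DMSO, 6 h with DMSO and 6 h with 2 h. The 35 gene lists and the rule for named genes were fixed before the data were examined. Some genes, such as MYC, CCND2, MCM4 and HSPD1, belong to more than 1 list, so the list calls are not independent of each other. Lists with at least 5 tested members (33) were tested with camera at a preset correlation of 0.01, with adjustment over the lists of a comparison. With an estimated correlation, camera bases its p on the 3 residual degrees of freedom of the fit. The preset and the estimated setting thus differ in more than the correlation. Myeloid and erythroid markers, with 4 and 2 tested members, were not tested. Named genes were the 8 largest rises and 8 largest falls of each comparison with DMSO, and 5 and 5 for 6 h with 2 h. They were taken among called genes with a mean of at least 4 CPM over all 6 libraries. Both libraries of one group also had to lie on one side of both libraries of the other. Up to 4 members of each called list with the smallest adjusted p were added, as were WNK1, WNK2, WNK3, WNK4, OXSR1, STK39, SLC12A2, MYC, IRF4, MAF, CCND2, PRDM1 and XBP1. Some genes that this rule takes in are not reported here. Levels are CPM with SD, and log2 changes are edgeR estimates with an SE derived from the F statistic of the test. Counting intervals and floors cover counting error only.

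The replicates of DMSO, 2 h and 6 h differed by more than sampling noise (chi-square per degree of freedom 9.17, 4.22 and 3.62). The procedure was tested on simulated data with 200 changed genes of 15548. Of changed genes of at least 4 CPM it recovered 19.4%, 59% and 100% at log2 changes of 0.3, 0.5 and 1, and 5 of 112 calls were false. In simulated unchanged libraries edgeR made 0 calls. Alternatives were other scalings, filters and tests (DESeq2 1.42.0, limma 3.58.1 voom), fits of only the groups compared, a replicate block, other thresholds, an estimated correlation, fry, and leaving out each library in turn. The simulations of unchanged groups with a library left out were added after seeing the data. A GC and length correction and a split of the DMSO libraries between the times were added after seeing the data. The gene families of the closing section, 12 kept of about 20 looked at, were chosen after seeing the data, and their symbol patterns were tightened after their first results were seen because they had caught unrelated genes. Those of translation initiation factors and of SR and hnRNP splicing factors still took in pseudogenes or other genes, so both families are left out of the text but were tested, and counted in the adjustment, with the rest. The limits used to judge the explanations weighed there were also set after the values were seen, except for GC content in the zinc-finger genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.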

Results

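The data were fragment counts per gene from 6 RNA-seq libraries of JJN3, a human multiple myeloma cell line. There were 3 groups of 2 libraries each: cells given the vehicle DMSO, cells given WNK463 for 2 h and cells given WNK463 for 6 h. WNK463 is a small-molecule inhibitor of the WNK kinases, which control cation-chloride cotransporters of the SLC12 family through the kinases OXSR1 and STK39. Counts assigned to genes totalled 18013790 and 21300013 in the DMSO libraries, 18713007 and 24002291 at 2 h, and 18959025 and 19264703 at 6 h. A count of 3 corresponded to between 0.125 and 0.167 CPM (counts scaled to library size). The correlation of log CPM between replicates was 0.984, 0.982 and 0.984 in the DMSO, 2 h and 6 h groups, against 0.966 to 0.976 between libraries of different groups. The first principal component held 38.9% of the variance and placed the 2 h libraries between DMSO and 6 h. The second, with 22.4%, set the 2 h libraries apart from the others. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries. The spread used for a gene was largely estimated over all genes, with 42.8 degrees of freedom against 3 from its own libraries. A very small p of a gene thus does not measure the spread of its own replicates. The sample titles give the DMSO libraries no collection time. Their count columns carry a 0 where those of the treated libraries carry 2 or 6, beside a letter that follows the replicate number. The series design speaks of 0, 2 and 6 h of WNK463 and the sample protocol of DMSO or WNK463 for 2 or 6 h. The 0 may mark collection at the start, but no label states this outright. Time in culture and treatment could not be separated. The dose is given as 5 µM in the sample protocol and 1 µM in the series design, and which holds is not given in the sources used here.

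The comparison of 2 h with DMSO asked which transcripts differed first after WNK463. Of 38 immediate early genes 22 were called higher at 2 h and 2 lower, of 22 ERK feedback genes 13 higher and 1 lower, and of 57 mitotic genes 0 higher and 32 lower. The 3 lists passed the list test camera at its preset correlation (largest adjusted p = 5.21e-16), and none passed with an estimated correlation (adjusted p = 0.0655, 0.0655 and 0.0803 in the order named). CCL3, a chemokine, rose 8.04-fold, from 1.55 ± 0.859 to 12.3 ± 2.17 CPM (SD, n = 2 per group). FOSL2, a subunit of the AP-1 transcription factor, rose 5.54-fold, from 5.35 ± 0.348 to 29.7 ± 3.36 CPM, and PHLDA1, an ERK-responsive gene, rose 3.99-fold, from 22.7 ± 0.820 to 90.6 ± 0.911 CPM. NEAT1, the noncoding scaffold of nuclear paraspeckles, fell from 426 ± 33.1 to 107 ± 4.87 CPM, a log2 change of -2.00. MYC fell from 854 ± 42.2 to 535 ± 1.91 CPM, a log2 change of -0.67. CCND2, a D-type cyclin of the cell cycle, rose 1.90-fold.

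Of 15548 genes tested, 2642 differed between 2 h and DMSO at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 1349 higher and 1293 lower, and 419 of them by a log2 change of at least 1. With library size alone as the scaling 1128 were higher and 1561 lower, so which direction held more genes depended on the scaling. The largest rises were taken among genes with a mean of at least 4 CPM over all 6 libraries. They were those of CCL3 (log2 change 3.01 ± 0.265 SE, adjusted p = 2.71e-12), the tight-junction gene CLDN4 (2.56), FOSL2 (2.47), MAFF (2.40), ZNF703 (2.28), the metallothionein MT2A (2.07), the cytokine signalling suppressor SOCS3 (2.03) and FRAT1 (2.00). MT2A passed this minimum through the 6 h libraries (10.7 CPM), with 0.903 CPM in DMSO and 3.87 CPM at 2 h. The largest falls were those of NEAT1 (-2.00 ± 0.0675, adjusted p = 2.68e-27), the noncoding gene ENSG00000268362, which has no symbol (-1.86), ZNF587B (-1.80), the microRNA host MIR17HG (-1.80), ZNF785 (-1.73), the snoRNA host SNHG4 (-1.67), the lysophospholipid acyltransferase gene LPCAT1 (-1.62 ± 0.0642) and MCM3AP-AS1 (-1.58). In each of these 16 genes both treated libraries lay outside the range of both DMSO libraries, as the rule for named genes required. On hg38, CCL3 (ENSG00000277632.2) spans chromosome 17 from 36088256 to 36090169. NEAT1 (ENSG00000245532.9) spans chromosome 11 from 65422774 to 65445540, and MYC (ENSG00000136997.20) chromosome 8 from 127735434 to 127742951. Counting ignored strand, and 74.6% of the exonic length of CCL3 is shared with the antisense gene CCL3-AS1 and 27.1% of that of ZNF785 with another antisense gene. CCL3 also has near-identical copies, so both levels are uncertain.

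Immediate early and ERK-responsive genes are induced within minutes to hours of a stimulus. Of 38 immediate early genes, 22 rose, 2 fell and 14 were not called (22 and 2 adjusted over the list alone), with a median log2 change of 0.81 (camera, adjusted p = 1.86e-22, and adjusted p = 0.0655 with an estimated correlation). RGS1 (2.82-fold), PLK3 (log2 change 1.31 ± 0.0969) and BTG1 (1.23 ± 0.0948) rose beside FOSL2, and BTG2 (-0.51) and DUSP2 (-0.53) fell. BTG2, DUSP2 and other members named for moving against their list were chosen after their values were seen. Of 22 genes of ERK feedback and MAPK output, 13 rose and 1, MYC, fell (13 and 2 adjusted over the list alone), with a median of 0.79 (adjusted p = 5.21e-16, and adjusted p = 0.0655 with an estimated correlation). PHLDA1 (2.00 ± 0.0971), BHLHE40 (1.16 ± 0.0827), MAFF and TRIB1 (0.74 ± 0.0726) were among those that rose. NF-kB targets gave 13 up and 4 down of 33 (15 and 4 adjusted over the list alone), among them JUNB (0.84), BIRC3 (0.50) and ICAM1 (0.77), at adjusted p = 4.03e-07 and adjusted p = 0.0655 with an estimated correlation. Targets of FOXO factors, which are active when PI3K signalling is low, gave 16 up and 1 down of 30 (16 and 3 adjusted over the list alone), among them TXNIP (1.04 ± 0.0659), KLHL24 (1.48 ± 0.105) and CCNG2 (1.40 ± 0.132), at adjusted p = 2.39e-08 and adjusted p = 0.0655 with an estimated correlation. The list of transcription regulators linked to super-enhancers gave 16 up and 4 down of 28 (17 and 5 adjusted over the list alone, adjusted p = 2.83e-08, and adjusted p = 0.0655 with an estimated correlation), with CCND2, HEXIM1 (0.76) and JUNB up and MYC and IRF4 down. The list was written in advance as regulators sensitive to transcription inhibition. How each member responds to such inhibition was not tested here, so these counts do not bear on it.

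Stress and survival lists were also called up at 2 h with the preset correlation, and not with an estimated one. Of 17 osmotic stress genes and targets of NFAT5, the transcription factor that responds to hypertonicity, 5 rose and 1 fell (5 and 2 adjusted over the list alone, adjusted p = 7.86e-05, and adjusted p = 0.0803 with an estimated correlation), with the amino acid transporter SLC38A2 at 1.62 ± 0.0567 and NFAT5 itself at 0.60 ± 0.0866. Integrated stress response genes gave 9 up and 3 down of 44 (10 and 4 adjusted over the list alone, adjusted p = 0.000274, and adjusted p = 0.103 with an estimated correlation), including SESN2 (1.04) and PPP1R15A (1.12), and ATF4 (-0.23) was among those that fell. Unfolded protein response genes gave 13 up and 2 down of 39 (13 and 3 adjusted over the list alone, adjusted p = 0.000278, and adjusted p = 0.0972 with an estimated correlation), including HERPUD1 (0.77) and DNAJB9 (1.01). Targets of p53 gave 8 up and 3 down of 26 (9 and 3 adjusted over the list alone, adjusted p = 0.00068, and adjusted p = 0.0915 with an estimated correlation), with the cell cycle inhibitor CDKN1A at 1.16 ± 0.0748. Apoptosis regulators, which hold members that promote and members that oppose cell death, gave 8 up and 3 down of 33 (9 and 4 adjusted over the list alone, adjusted p = 0.00682, and adjusted p = 0.103 with an estimated correlation). Those that rose included the pro-death genes BBC3 (1.85 ± 0.195) and BMF (0.79) and the pro-survival genes BIRC3 and BCL2 (0.34). Glycolysis and hypoxia genes gave 9 up and 1 down of 40 (11 and 1 adjusted over the list alone, adjusted p = 0.000232, and adjusted p = 0.123 with an estimated correlation), including SLC2A1 (0.52), DDIT4 (0.80) and NDRG1 (0.29). DDIT4 shares 41.2% of its exonic length with DDIT4-AS1 and ICAM1 25.4% with antisense genes.

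So were lists of surface, differentiation and lipid-sensing genes, again not with an estimated correlation. TGF-beta and SMAD targets gave 10 up and 0 down of 20 (10 and 0 adjusted over the list alone, adjusted p = 8.72e-06, and adjusted p = 0.0758 with an estimated correlation), including SMAD7 (1.08 ± 0.126) and TGFBR1 (0.76). Genes of the MAF program, driven by the transcription factor MAF in a subset of myeloma, gave 6 up and 0 down of 13 (7 and 0 adjusted over the list alone, adjusted p = 1.98e-05, and adjusted p = 0.0792 with an estimated correlation), with CCND2 at 0.92 ± 0.0630 and CCR1 at 0.55. Adhesion, chemokine receptor and migration genes gave 10 up and 0 down of 33 (10 and 0 adjusted over the list alone, adjusted p = 4.42e-05, and adjusted p = 0.0929 with an estimated correlation), including RHOB (0.84) and CD44 (0.44). Targets of liver X receptors, the sterol-sensing nuclear receptors, gave 5 up and 0 down of 8 (6 and 0 adjusted over the list alone, adjusted p = 0.000228, and adjusted p = 0.111 with an estimated correlation), with the sterol exporter ABCA1 at 0.88 ± 0.115. ABCG1 had 1 count over both DMSO libraries and 38 at 2 h, a ratio of 35.7 with a 95% counting interval of 6.04 to 1450. The 8 epithelial markers, a check for other cells, gave 3 up and 0 down (4 and 0 adjusted over the list alone, adjusted p = 0.014, and adjusted p = 0.231 with an estimated correlation): CLDN4, EPCAM (0.29) and CDH1 (0.61). That call was lost without DMSO replicate 1 (adjusted p = 0.102), DMSO replicate 2 (0.0737), 2 h replicate 1 (0.215) or 6 h replicate 2 (0.0557). Without 2 h replicate 2 the rise of EPCAM was not called (adjusted p = 0.195), and that of CDH1 was lost under 11 alternatives (0.0565 to 0.307).

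Of 57 G2-M and mitosis genes, 32 fell, 0 rose and 25 were not called (37 and 0 adjusted over the list alone), with a median log2 change of -0.27 (adjusted p = 1.37e-16, and adjusted p = 0.0803 with an estimated correlation). ASPM (-0.80 ± 0.0769), KIF20B (-0.74 ± 0.0883), CDCA8 (-0.69) and NDC80 (-0.68) are genes of the mitotic spindle and kinetochore. MYC targets and ribosome biogenesis genes gave 13 down and 0 up of 59 (13 and 0 adjusted over the list alone), with a median of -0.11 (adjusted p = 0.000637, and adjusted p = 0.123 with an estimated correlation), including RRS1 (-0.62) and NOP16 (-0.56). Cholesterol synthesis genes and SREBP targets gave 10 down and 2 up of 34 (11 and 2 adjusted over the list alone, adjusted p = 0.00901, and adjusted p = 0.103 with an estimated correlation), including HMGCS1 (-0.52) and SCD (-0.42). HMGCS1 shares 37.7% of its exonic length with an antisense gene. No list passed at 2 h with an estimated correlation (0 of 33 in camera, 16 at an unadjusted p under 0.05), against 21 with the preset correlation and 25 in the rotation test fry. Without 2 h replicate 2 the number of genes called fell to 1527.

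**Figure D1:**
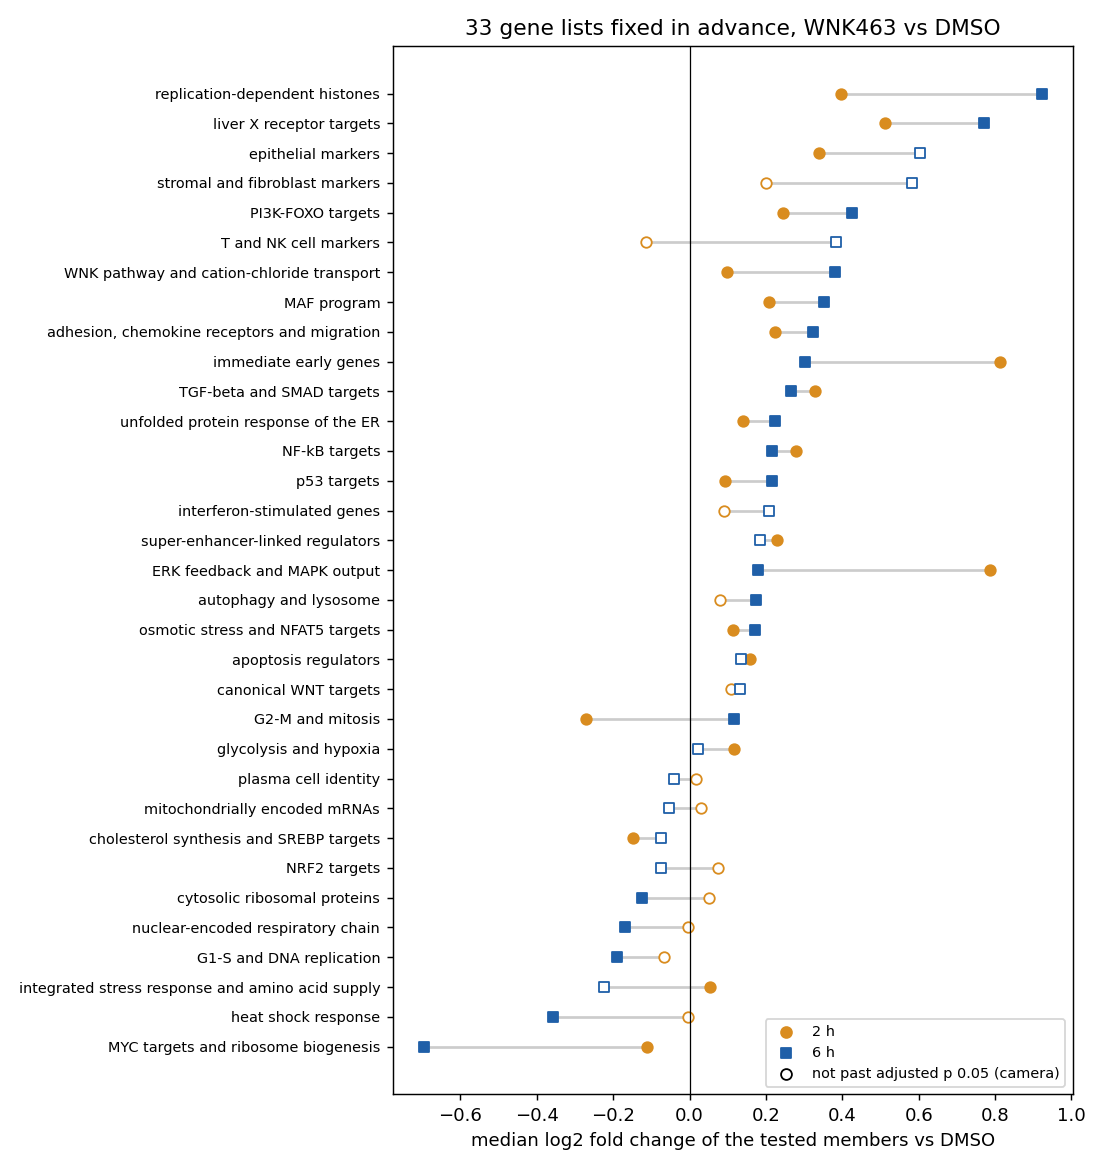
Median log2 change against DMSO (x axis) of the tested members of each of 33 gene lists (y axis), at 2 h (orange circles) and at 6 h (blue squares), filled where the list passed camera at an adjusted p under 0.05 and open where it did not. The MYC and ribosome biogenesis list moved from -0.11 to -0.70, the immediate early list from 0.81 to 0.30, and the G2-M list from -0.27 to 0.12.

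The comparison of 6 h with DMSO covered the later change. Of 59 MYC targets and ribosome biogenesis genes 56 were called lower and 1 higher, of 31 heat shock genes 22 lower and 4 higher, and of 55 genes of G1-S and DNA replication 22 lower and 8 higher. Of 52 autophagy and lysosome genes 21 were called higher and 2 lower, and of 29 genes of the WNK pathway and cation-chloride transport 15 higher and 4 lower. All 5 lists passed camera at its preset correlation (largest adjusted p = 0.00456), but with an estimated correlation only the ribosome biogenesis list did (adjusted p = 0.0401, against 0.0823 for heat shock and 0.121 for each of the others). CDKN1C, an inhibitor of cyclin-dependent kinases, rose 7.32-fold, from 9.75 ± 0.625 to 71.3 ± 1.83 CPM (SD, n = 2 per group), and MT2A rose 11.7-fold, from 0.903 ± 0.259 to 10.7 ± 0.593 CPM. HSPA8, the constitutive HSP70 chaperone, fell from 3865 ± 194 to 1594 ± 10.5 CPM, a log2 change of -1.28. COL5A1, a collagen chain, fell from 116 ± 31.5 to 14.8 ± 0.928 CPM, and MYC from 854 ± 42.2 to 463 ± 1.5 CPM.

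At 6 h, 5693 genes differed from DMSO, 2795 higher and 2898 lower, and 953 by a log2 change of at least 1. With library size alone 3067 were higher and 2540 lower. The largest rises were those of MT2A (3.54 ± 0.308, adjusted p = 4.58e-13), SPRR2A (3.08), CDKN1C (2.87 ± 0.128, adjusted p = 7.46e-23), CCL3 (2.79), the lactoferrin gene LTF (2.65), the kinase gene TESK1 (2.28), the glycosyltransferase gene B3GNT7 (2.25) and the chemokine gene CCL5 (2.19). The largest falls were those of COL5A1 (-2.97 ± 0.124, adjusted p = 6.14e-24), the WNT ligand gene WNT10B (-2.56), SNHG26 (-2.27), FUBP1, which encodes a DNA-binding activator of MYC (-2.01 ± 0.0667, adjusted p = 1.21e-27), ARHGAP22 (-1.88), FAM222A-AS1 (-1.82), the necroptosis effector gene MLKL (-1.76) and the tRNA methyltransferase gene TRMT61A (-1.74). All 16 lay outside the DMSO range in both treated libraries, again as that rule required. CDKN1C (ENSG00000129757.13) spans chromosome 11 from 2883213 to 2885773. MT2A (ENSG00000125148.7) spans chromosome 16 from 56608584 to 56609497, and COL5A1 (ENSG00000130635.16) chromosome 9 from 134641803 to 134844843.

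Lists of ribosome biogenesis, heat shock, ribosomal protein, respiratory chain and DNA replication genes were called down at 6 h with the preset correlation, and only the first also with an estimated one. Of 59 MYC targets and ribosome biogenesis genes, 56 fell, 1 (PLK4, 0.36) rose and 2 were not called (56 and 1 adjusted over the list alone), with a median log2 change of -0.70. This list passed with the preset and with an estimated correlation (adjusted p = 2.84e-48 and 0.0401). MYBBP1A (-1.28 ± 0.0717), MRTO4 (-1.22 ± 0.0718) and UTP20 (-1.21 ± 0.0759) encode nucleolar proteins. Of 31 heat shock genes, 22 fell, 4 rose and 5 were not called (23 and 4 adjusted over the list alone, adjusted p = 2.83e-08, and adjusted p = 0.0823 with an estimated correlation). The falls included those of HSPA8 (-1.28 ± 0.0446), HSPD1 (-0.51) and TCP1 (-0.51), and DNAJB4 (0.68), DNAJB6 (0.28), HSF2 (0.31) and SERPINH1 (0.70) rose. Cytosolic ribosomal protein genes gave 31 down and 1 up of 76 (35 and 1 adjusted over the list alone), with a median of -0.12 (adjusted p = 0.00129, adjusted p = 0.506 with an estimated correlation, and 0.0874 in fry). RPL8 (-0.30) and RPL23A (-0.26) were among those that fell. RPL8 was not called without DMSO replicate 1 (-0.06, adjusted p = 0.152) and stood at -0.51 without DMSO replicate 2. RPL23A stood at -0.15 without DMSO replicate 1. In DESeq2 neither was called (adjusted p = 0.212 for RPL8 and 0.0649 for RPL23A), nor was RPL8 with robust dispersions (0.249). Reads of ribosomal protein genes are partly ambiguous with pseudogenes. Nuclear-encoded respiratory chain genes gave 26 down and 2 up of 69 (26 and 2 adjusted over the list alone), including CYC1 (-0.39) and ATP5PB (-0.31), at adjusted p = 0.00307, adjusted p = 0.368 with an estimated correlation and 0.0581 in fry. G1-S and DNA replication genes gave 22 down and 8 up of 55 (27 and 8 adjusted over the list alone, adjusted p = 0.00456, and adjusted p = 0.121 with an estimated correlation), with MCM4 (-0.70) and GINS2 (-0.96) down.

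Lists of transport, sterol-sensing, lysosome and secretory genes were called up at 6 h with the preset correlation, and not with an estimated one. Of 29 genes of the WNK pathway and cation-chloride transport, 15 rose, 4 fell and 10 were not called (16 and 4 adjusted over the list alone), with a median log2 change of 0.38 (adjusted p = 0.000403, and adjusted p = 0.121 with an estimated correlation). They included the volume-regulated anion channel subunit LRRC8C (0.76 ± 0.0749), NRBP1 (0.73 ± 0.0731) and WNK1 (0.57 ± 0.0599). WNK2 (-1.08), SLC12A7 (-0.31), LRRC8D (-0.47) and CLNS1A (-0.46) fell. Osmotic stress and NFAT5 targets gave 6 up and 3 down of 17 (6 and 3 adjusted over the list alone, adjusted p = 0.00486, and adjusted p = 0.13 with an estimated correlation), with SLC38A2 at 1.55 ± 0.0567 and the taurine transporter SLC6A6 at 0.56. Liver X receptor targets gave 6 up and 0 down of 8 (7 and 0 adjusted over the list alone, adjusted p = 1.84e-05, and adjusted p = 0.121 with an estimated correlation), with ABCA1 at 1.66 ± 0.113 and SREBF1 at 0.72. ABCG1 had 65 counts against 1, a ratio of 65.3 with a 95% counting interval of 11.3 to 2620. Autophagy and lysosome genes gave 21 up and 2 down of 52 (21 and 2 adjusted over the list alone, adjusted p = 0.000225, and adjusted p = 0.121 with an estimated correlation), including the protease gene CTSB (1.02 ± 0.0702) and the autophagy receptor gene SQSTM1 (0.56). Unfolded protein response genes gave 21 up and 5 down of 39 (22 and 6 adjusted over the list alone, adjusted p = 0.000363, and adjusted p = 0.121 with an estimated correlation), including SEL1L (0.73) and SYVN1 (0.64) of the ER degradation machinery, while XBP1 fell.

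Several lists called up at 2 h were also called up at 6 h with the preset correlation, and not with an estimated one. FOXO targets gave 16 up and 2 down of 30 (16 and 2 adjusted over the list alone, adjusted p = 1.33e-07, and adjusted p = 0.0823 with an estimated correlation), with CCNG2 at 1.81 ± 0.132. Immediate early genes gave 16 up and 1 down of 38 (17 and 1 adjusted over the list alone, adjusted p = 0.000193, and adjusted p = 0.183 with an estimated correlation). ERK feedback genes gave 8 up and 2 down of 22 (8 and 2 adjusted over the list alone, adjusted p = 0.00633, and adjusted p = 0.135 with an estimated correlation). Adhesion genes gave 11 up and 2 down of 33 (12 and 2 adjusted over the list alone, adjusted p = 0.00088, and adjusted p = 0.135 with an estimated correlation), with the chemokine receptors CCR1 (1.39 ± 0.0686) and CCR2 (1.45 ± 0.143) up. Genes of the MAF program gave 6 up and 0 down of 13 (7 and 0 adjusted over the list alone, adjusted p = 0.00088, and adjusted p = 0.121 with an estimated correlation). ITGB7 (0.48) was among them, and 42.3% of its exonic length is shared with ZNF740. NF-kB targets gave 14 up and 3 down of 33 (15 and 3 adjusted over the list alone, adjusted p = 0.00483, and adjusted p = 0.121 with an estimated correlation), including CXCL8 (2.16 ± 0.196). Targets of p53 gave 11 up and 4 down of 26 (11 and 4 adjusted over the list alone, adjusted p = 0.00449, and adjusted p = 0.121 with an estimated correlation). TGF-beta targets gave 9 up and 0 down of 20 (9 and 0 adjusted over the list alone, adjusted p = 0.0252, and adjusted p = 0.157 with an estimated correlation).

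Of 57 G2-M and mitosis genes, 24 were higher than DMSO at 6 h, 6 were lower and 27 were not called (26 and 6 adjusted over the list alone), with a median of 0.12 (adjusted p = 0.0272, and adjusted p = 0.368 with an estimated correlation). KIF2C (0.55), CKAP2 (0.53), HJURP (0.61) and HMMR (0.51) rose. The list was not called without DMSO replicate 1 (adjusted p = 0.087). Replication-dependent histone genes, whose transcripts mostly lack poly(A) tails and which were listed as a check of RNA selection, gave 10 up and 0 down of 24 at 6 h (10 and 0 adjusted over the list alone), with a median of 0.92 (adjusted p = 0.000307, and adjusted p = 0.135 with an estimated correlation). H2BC21 rose by 1.99 ± 0.162 and H4C8 by 1.45 ± 0.217, although near-identical copies make single histone genes uncertain. At 2 h 3 histone genes rose (3 adjusted over the list alone, adjusted p = 0.0391, and adjusted p = 0.254 with an estimated correlation), a call lost without either DMSO replicate, without 2 h replicate 2 or without either 6 h library (adjusted p 0.0526 to 0.124), and with the GC and length correction (0.0742).

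**Figure D2:**
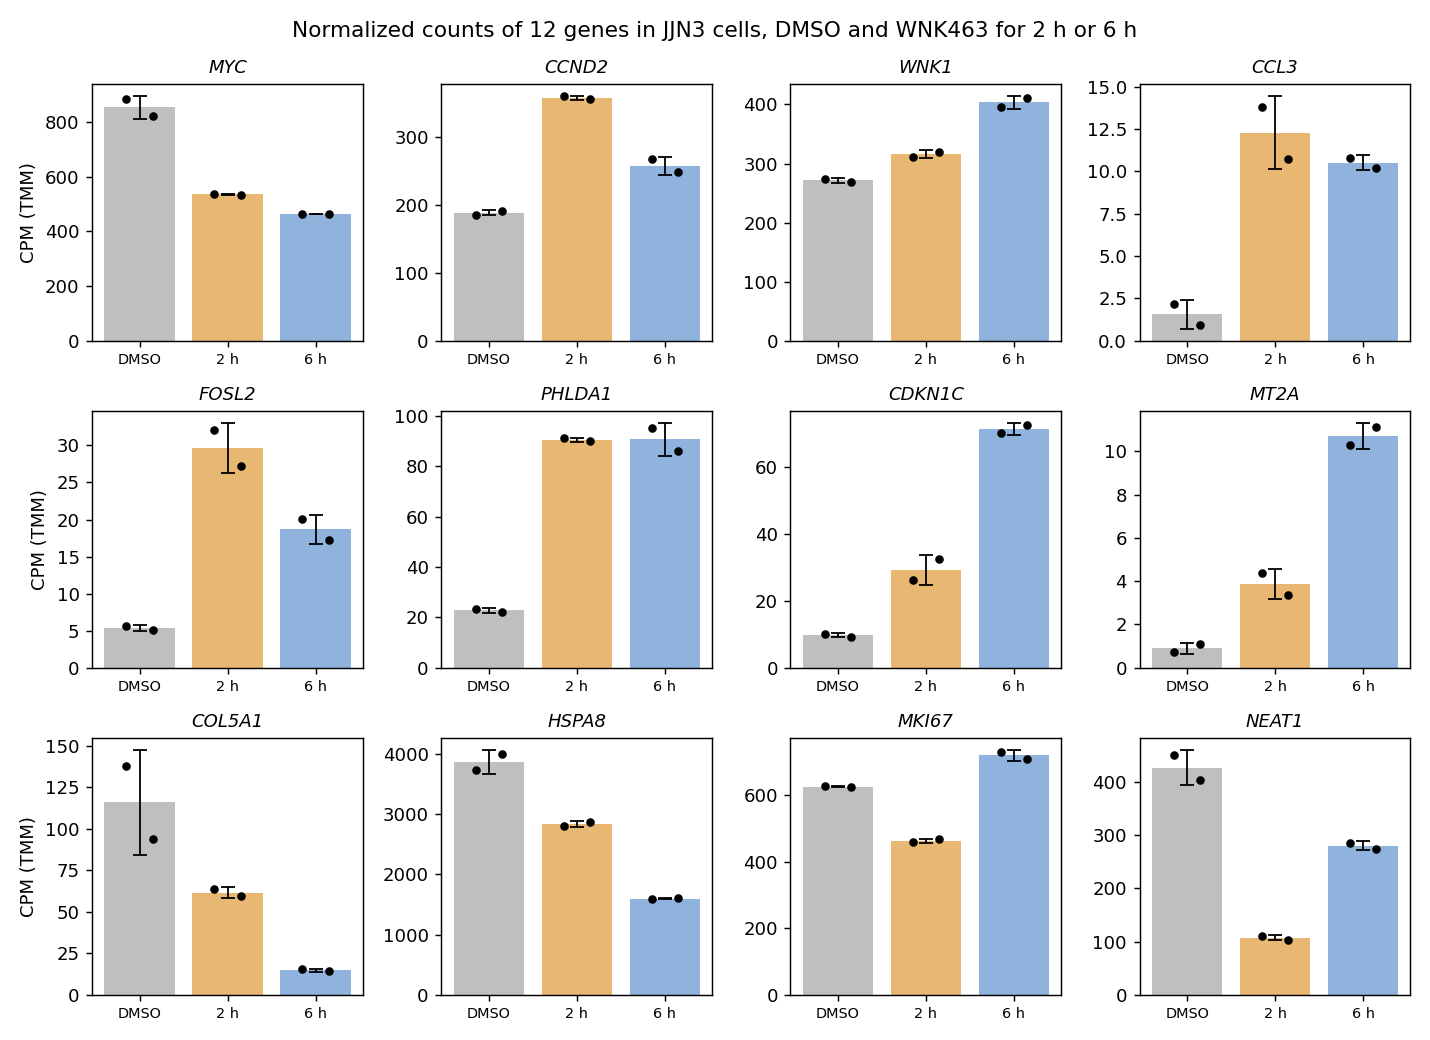
Level in CPM (y axis of each panel) of 12 genes in the DMSO, 2 h and 6 h groups (x axis), with bars at the mean, error bars of 1 SD and both libraries as points (n = 2 per group). MYC went from 854 to 535 and 463 CPM, CDKN1C from 9.75 to 71.3 CPM at 6 h, and NEAT1 from 426 to 107 CPM at 2 h.

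The comparison of 6 h with 2 h tested directly which changes differed between the times. Of 57 mitotic genes 42 were called higher at 6 h than at 2 h and 0 lower, and 54 of 59 MYC targets and ribosome biogenesis genes, 21 of 31 heat shock genes and 21 of 44 genes of the integrated stress response and amino acid supply were called lower. All 4 lists passed camera at its preset correlation (largest adjusted p = 2.38e-08), but with an estimated correlation only the ribosome biogenesis list did (adjusted p = 0.0293, against 0.107 for the mitotic list, 0.0568 for heat shock and 0.107 for amino acid supply). MKI67, the proliferation marker, rose 1.55-fold, from 463 ± 5.50 to 720 ± 15.8 CPM (SD, n = 2 per group), and HJURP, a centromere chaperone, rose 2.01-fold. SLC7A5, a subunit of the main leucine transporter, fell from 1163 ± 16.8 to 632 ± 12.8 CPM. In all, 3772 genes differed, 1731 higher and 2041 lower, of which 316 by a log2 change of at least 1. The share higher was 45.9% with TMM scaling and 61.3% with library size alone. Without a 6 h library the count fell to 2288 (replicate 1) or 2372 (replicate 2).

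The largest rises from 2 h to 6 h were those of the dynein adaptor gene BICDL1 (1.83 ± 0.215, adjusted p = 5.7e-09), SPRR2A (1.57), MXD3, a MAX-binding antagonist of MYC (1.51 ± 0.151), PAQR6 (1.49) and MT2A (1.48). The largest falls were those of WNT10B (-2.33 ± 0.314), COL5A1 (-2.05 ± 0.125), the lysophospholipid transporter gene MFSD2A (-1.86), ARHGAP22 (-1.73) and GBP1 (-1.70). MXD3 shares 40.2% of its exonic length with PRELID1 and RAB24, so its level is uncertain. Of 57 mitotic genes, 42 rose and 0 fell (42 and 0 adjusted over the list alone), with a median of 0.42 (adjusted p = 4.35e-26, and adjusted p = 0.107 with an estimated correlation). CKAP2 rose by 0.94 ± 0.0757, NDC80 by 0.89 and MKI67 by 0.64 ± 0.0540. Of 59 MYC targets and ribosome biogenesis genes, 54 fell and 1, PLK4, rose (56 and 1 adjusted over the list alone), with a median of -0.59, in a list that passed with both correlations (adjusted p = 4.12e-57 and 0.0293). SRM (-0.81), DDX21 (-0.76) and MYBBP1A (-1.05) were among them. Heat shock genes gave 21 down and 1 up of 31 (22 and 1 adjusted over the list alone, adjusted p = 1.16e-12, and adjusted p = 0.0568 with an estimated correlation), with HSPA8 at -0.83 ± 0.0443. Genes of the integrated stress response and amino acid supply gave 21 down and 2 up of 44 (22 and 2 adjusted over the list alone, adjusted p = 2.38e-08, and adjusted p = 0.107 with an estimated correlation), including SLC7A5 (-0.88 ± 0.0514), SLC1A5 (-0.63) and GARS1 (-0.50).

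Further lists were called lower at 6 h than at 2 h with the preset correlation, and not with an estimated one. Cytosolic ribosomal protein genes gave 50 down and 0 up of 76 (64 and 0 adjusted over the list alone), with a median of -0.17 (adjusted p = 9.55e-10, and adjusted p = 0.37 with an estimated correlation), including RPL13 (-0.26). Respiratory chain genes gave 15 down and 0 up of 69 (14 and 0 adjusted over the list alone, adjusted p = 0.000307, adjusted p = 0.372 with an estimated correlation, and 0.0684 in fry). Targets of NRF2, the antioxidant transcription factor, gave 12 down and 1 up of 25 (13 and 1 adjusted over the list alone, adjusted p = 0.000484, and adjusted p = 0.107 with an estimated correlation), including ME1 (-0.66) and TKT (-0.55). ERK feedback genes gave 12 down and 1 up of 22 (13 and 1 adjusted over the list alone, adjusted p = 0.000613, and adjusted p = 0.107 with an estimated correlation), including DUSP5 (-0.59). Immediate early genes gave 13 down and 1 up of 38 (15 and 1 adjusted over the list alone, adjusted p = 0.000707, and adjusted p = 0.26 with an estimated correlation), including EGR1 (-0.91 ± 0.176). G1-S genes gave 17 down and 4 up of 55 (19 and 6 adjusted over the list alone, adjusted p = 0.00222, and adjusted p = 0.107 with an estimated correlation). Super-enhancer-linked regulators gave 12 down and 1 up of 28 (12 and 1 adjusted over the list alone, adjusted p = 0.0035, and adjusted p = 0.134 with an estimated correlation), including CCND2 (-0.47) and PIM3 (-0.64). Glycolysis and hypoxia genes gave 14 down and 4 up of 40 (16 and 4 adjusted over the list alone, adjusted p = 0.0221, and adjusted p = 0.352 with an estimated correlation), a call lost without 2 h replicate 1 (0.0501) and with library size alone (0.0574).

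Lists of autophagy, sterol-sensing and histone genes were called higher at 6 h than at 2 h, again not with an estimated correlation. Autophagy and lysosome genes gave 13 up and 1 down of 52 (17 and 1 adjusted over the list alone, adjusted p = 0.00105, and adjusted p = 0.107 with an estimated correlation), including ULK1, the kinase that starts autophagy (0.89 ± 0.115). Liver X receptor targets gave 3 up and 0 down of 8 (3 and 0 adjusted over the list alone, adjusted p = 0.0146, and adjusted p = 0.248 with an estimated correlation), with ABCA1 at 0.78. Histone genes gave 6 up and 0 down of 24 (6 and 0 adjusted over the list alone, adjusted p = 0.00323, and adjusted p = 0.226 with an estimated correlation), with H2BC21 at 1.05. Lists not called between the times but past the threshold under an alternative were the WNK pathway (8 up and 5 down of 29, adjusted p = 0.0733, and 0.0338 with library size alone), the unfolded protein response (9 up and 4 down of 39, 0.169, and 0.0365 with library size alone), FOXO targets (8 up and 1 down of 30, 0.0641) and interferon-stimulated genes (4 up and 2 down of 27, 0.0747). FOXO targets passed with library size alone (0.0379) and without DMSO replicate 1 (0.048), 2 h replicate 1 (0.0443) or 6 h replicate 1 (0.0499), and interferon-stimulated genes without 2 h replicate 2 (0.0447) or 6 h replicate 1 (0.0499). The rotation test fry, which does not compare a list with other genes, called these 4 lists (0.00429 to 0.0173) and also TGF-beta targets (0.00661), NF-kB targets (0.0112), cholesterol synthesis (0.0112), plasma cell identity (0.0257) and stromal markers (0.0339).

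Across both times, 1019 genes were higher than DMSO and 795 lower in the 2 h and the 6 h libraries alike. In simulated unchanged groups set against shared, likewise simulated DMSO libraries both numbers were 0. That says nothing of how many genes that changed at each time on its own would coincide. Independent lists of the sizes called would share 242.5 genes higher and 241 lower, but noise shared through the DMSO libraries can also raise the overlap. The log2 changes at 2 h and 6 h correlated across genes at 0.627, and genes are not independent replicates. Unchanged groups simulated against shared, likewise simulated DMSO libraries gave 0.506 (0.473 to 0.526 in 20 simulations). That simulation gave all groups the same spread, while the real replicates differed most in DMSO (chi-square per degree of freedom 9.17, against 4.22 at 2 h and 3.62 at 6 h). It therefore cannot show whether 0.627 exceeds what noise shared through the controls would give. The covariance was 0.289, against 0.0848 simulated. With the controls split, so that each time was set against a different DMSO library, the correlation was 0.331 and 0.323 in the respective arrangements and the covariance 0.222 in each. Each change then rests on a single DMSO library, and this split was chosen after seeing the data. With a library left out the correlation was 0.449 and 0.437 (without 2 h replicates 1 and 2), where unchanged groups simulated for the same design gave 0.385 to 0.423 and 0.347 to 0.398. It was 0.76 without DMSO replicate 1, against 0.681 to 0.71 simulated, and 0.697 without DMSO replicate 2, below the 0.716 to 0.758 simulated, so the correlation did not exceed that of unchanged groups in every design. The covariance without DMSO replicate 2 was 0.692, against 0.435 to 0.52 simulated. Without 2 h replicate 2 the genes called at both times in the same direction numbered 1110 in place of 1814. A change in opposite directions was called for 46 genes, 21 up at 2 h and down at 6 h and 25 down at 2 h and up at 6 h. That number was 25 and 22 without 2 h replicates 1 and 2, 20 and 22 without 6 h replicates 1 and 2, and 83 without DMSO replicate 2. With the GC and length correction it was 109. At 6 h alone, with 6 h also differing from 2 h, 900 genes were higher and 1317 lower. At 2 h alone, with the same test of the times, 134 were higher and 233 lower.

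**Figure D3:**
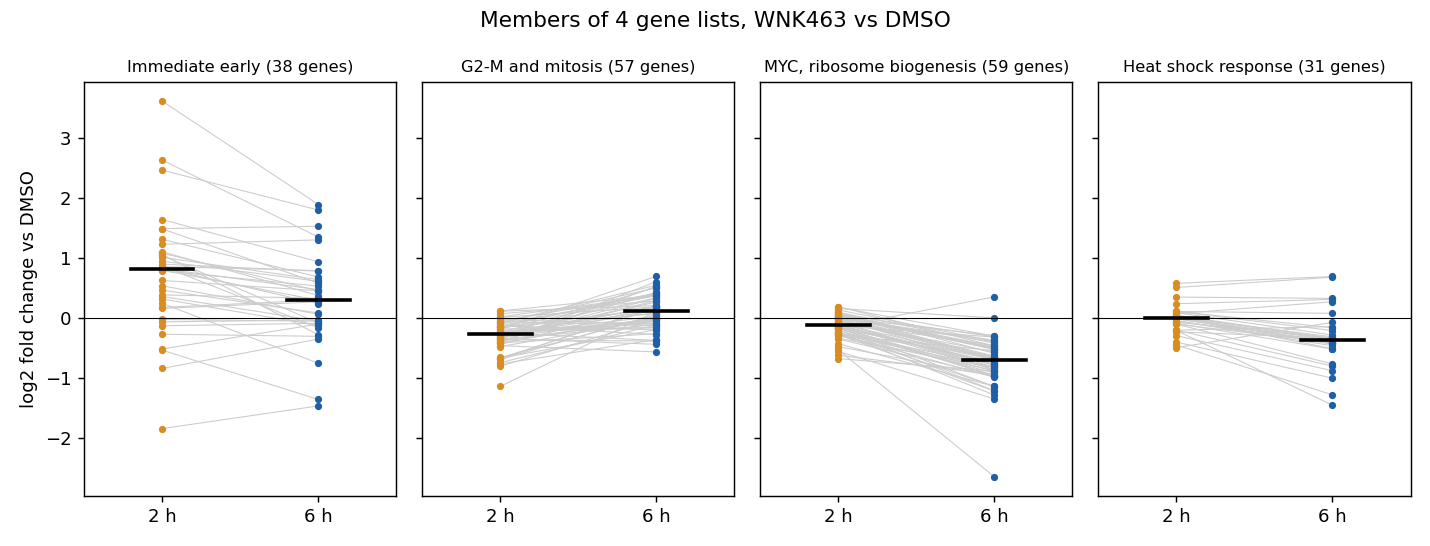
Log2 change against DMSO (y axis) of each tested member of 4 lists (immediate early, 38 genes; G2-M, 57; MYC and ribosome biogenesis, 59; heat shock, 31) at 2 h and 6 h (x axis), with a black bar at the median. At 6 h 56 of 59 MYC and ribosome biogenesis genes were called lower, and the G2-M median went from -0.27 to 0.12.

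Among the genes followed in every comparison, WNK1 (ENSG00000060237.17, chromosome 12 from 752579 to 911452), the main WNK kinase of these cells by count, was 0.22 ± 0.0599 above DMSO at 2 h, a call lost without 2 h replicate 2 (adjusted p = 0.15), and 0.57 ± 0.0599 at 6 h. WNK2 had a log2 change of -0.07 at 2 h (adjusted p = 0.822, and a log2 change of 0.05 without DMSO replicate 1) and fell by 1.08 at 6 h. WNK3 had 12 counts and WNK4 3 counts over all 6 libraries, too few to test. STK39 stood at 0.21 at 2 h (adjusted p = 0.112), or 0.37 without DMSO replicate 2 (adjusted p = 0.00233) and 0.08 without DMSO replicate 1. It passed with the GC and length correction (0.0407) and rose by 0.49 at 6 h. OXSR1 differed from DMSO at neither time (adjusted p = 0.595 and 0.184). The sodium-potassium-chloride cotransporter gene SLC12A2 rose by 0.26 at 2 h (adjusted p = 0.0384) and 0.42 at 6 h, the first call being lost without DMSO replicate 2 (0.0563), 2 h replicate 2 (0.449), 6 h replicate 1 (0.0698) or 6 h replicate 2 (0.0682). That call was also lost with library size alone (0.0726), no filter (0.0541), DESeq2 (0.0625) and only the groups compared (0.0615). At 2 h the WNK pathway list as a whole gave 9 up and 1 down of 29 (9 and 1 adjusted over the list alone). Its adjusted p in camera was 0.00195, and 0.0929 with an estimated correlation. Those up included the kinase SGK1 (1.65 ± 0.183), LRRC8C (0.67) and TSC22D1 (0.95). SGK1 and TSC22D1 also belong to the immediate early list, which was called up at 2 h with the preset correlation.

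Of the myeloma regulators followed in every comparison, MYC had log2 changes of -0.67 ± 0.0545 at 2 h and -0.88 ± 0.0547 at 6 h. IRF4, a transcription factor of plasma cells, stood at -0.27 and -0.28. PRDM1, the plasma cell repressor, rose by 0.34 and 0.42. CCND2 rose by 0.92 at 2 h and 0.45 at 6 h, and MAF stood at 0.19 (adjusted p = 0.0105) and -0.08 (adjusted p = 0.237), the 2 h call being lost without 2 h replicate 1 (0.11) or 2 (0.12). XBP1 had a log2 change of -0.12 at 2 h (adjusted p = 0.24, and 0.0257 without DMSO replicate 1) and fell by 0.33 at 6 h. The plasma cell identity list was not called at any comparison, with 6 up and 3 down of 26 at 2 h (adjusted p = 0.105), 7 up and 7 down at 6 h (0.752, with a median of -0.04 and a mean of 0.01), and 4 up and 5 down between the times (0.36).

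Of the remaining lists, T and NK cell markers gave 1 up of 6 at 2 h (adjusted p = 0.71, median -0.11 and mean 0.20) and 2 up and 1 down at 6 h (0.569). Stromal markers gave 0 up and 0 down of 7 at 2 h (0.405) and 1 up at 6 h (0.262). The epithelial list was not called at 6 h (4 up and 0 down, adjusted p = 0.0598). Mitochondrially encoded mRNAs, a check of RNA quality, gave 2 up and 0 down of 13 at 2 h (0.477) and 2 up and 4 down at 6 h (0.649). The share of counts from mitochondrial genes was 4.43% and 5.14% in DMSO, 4.96% and 5.14% at 2 h, and 5.16% and 5.24% at 6 h. Interferon-stimulated genes gave 2 up and 2 down of 27 at 2 h (0.664) and 9 up and 2 down at 6 h (0.0821). Canonical WNT targets gave 2 up and 2 down of 10 (0.477) and 3 up and 3 down (0.465), where the median (0.11 and 0.13) and the test, which pointed down, differed in sign. Not called at 2 h alone were heat shock (2 up, 2 down, 0.664), G1-S (4 up, 7 down, 0.531), autophagy (10 up, 2 down, 0.0722), ribosomal protein (11 up, 1 down, 0.0534) and respiratory chain genes (1 up, 0 down, 0.832). Some 2 h lists passed under alternatives. When a DMSO library was left out they were ribosomal protein genes (7.52e-07), NRF2 targets (0.047) and mitochondrial mRNAs (0.0261) without replicate 1, and autophagy genes (0.0259) and mitochondrial mRNAs (2e-06) without replicate 2. Ribosomal protein genes also passed with RLE scaling (0.0435), the GC and length correction (0.0295) and without 2 h replicate 2 (0.0166), and autophagy genes with the GC and length correction (0.0245). At 6 h this held for mitochondrial mRNAs (0.00275) without DMSO replicate 1, the integrated stress response (0.00773) and NRF2 targets (0.0289) without DMSO replicate 2, and epithelial markers without 6 h replicate 1 (0.0374) or with a filter of 1 CPM (0.0345). In fry the lists gained at 2 h were autophagy genes (0.0123), plasma cell identity (0.0169), stromal markers (0.0202) and NRF2 targets (0.0225). Those gained at 6 h were interferon-stimulated genes (0.00121), cholesterol synthesis (0.00211), stromal markers (0.00411), super-enhancer-linked regulators (0.00411), NRF2 targets (0.00486), apoptosis regulators (0.0125), epithelial markers (0.0138), WNT targets (0.0285) and the integrated stress response (0.037). NRF2 targets were not called at 2 h (3 up, 2 down, 0.161) or at 6 h (4 up, 10 down, 0.0821). At 6 h the integrated stress response list (8 up, 20 down, 0.0849, with a median of -0.22 and a mean of 0.01), apoptosis regulators (14 up, 6 down, 0.0821), cholesterol synthesis (9 up, 8 down, 0.285), glycolysis (12 up, 14 down, 0.514) and super-enhancer-linked regulators (12 up, 8 down, 0.136) were not called.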

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

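The tests of explanations below, except that of GC content in the zinc-finger genes, were chosen only after the results were seen. They covered GC content, scaling, time in culture, a general stop of RNA synthesis, nuclear RNA, RNA without poly(A) tails and S phase. Each value in the following 3 paragraphs is a result whose change from DMSO differed between 2 h and 6 h by the direct test of the times, given as the adjusted p of a list, with the preset correlation and then with an estimated correlation, or the log2 difference of a gene, 6 h minus 2 h.

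Of 15 lists called between the times with the preset correlation, MYC targets and ribosome biogenesis (4.12e-57, and adjusted p = 0.0293 with an estimated correlation) was the only list that also passed with an estimated correlation. The others were G2-M and mitosis (4.35e-26, and adjusted p = 0.107 with an estimated correlation), heat shock (1.16e-12, and 0.0568), cytosolic ribosomal proteins (9.55e-10, and 0.37) and the integrated stress response (2.38e-08, and 0.107). Further lists were the respiratory chain (0.000307, and adjusted p = 0.372 with an estimated correlation), NRF2 targets (0.000484, and 0.107), ERK feedback (0.000613, and 0.107), immediate early genes (0.000707, and 0.26) and autophagy and lysosome (0.00105, and 0.107). The last were G1-S (0.00222, and adjusted p = 0.107 with an estimated correlation), histones (0.00323, and 0.226), super-enhancer-linked regulators (0.0035, and 0.134), liver X receptor targets (0.0146, and 0.248) and glycolysis and hypoxia (0.0221, and 0.352), the last of these lost without 2 h replicate 1 (0.0501) and with library size alone (0.0574). Of single genes, 21 were up at 2 h and down at 6 h, such as HES1 (0.83 and -0.88) and RGS16 (0.44 and -1.08), and 25 were down at 2 h and up at 6 h, such as HMGCS1 (-0.52 and 0.24). These examples were chosen after their values were seen, and the respective numbers add to 46, against 20 to 83 with a library left out (20 without 6 h replicate 1, 83 without DMSO replicate 2) and 109 with the GC and length correction.

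The genes with the largest differences were BICDL1 (1.83), SPRR2A (1.57), MXD3 (1.51), PAQR6 (1.49), MT2A (1.48), WNT10B (-2.33), COL5A1 (-2.05), MFSD2A (-1.86), ARHGAP22 (-1.73) and GBP1 (-1.70). Lower at 6 h in the MYC and ribosome biogenesis list were MYBBP1A (-1.05), UTP20 (-1.03), SRM (-0.81) and DDX21 (-0.76). In amino acid supply they were SLC7A5 (-0.88), SLC7A1 (-0.64), SLC1A5 (-0.63) and GARS1 (-0.50). Immediate early and ERK genes lower at 6 h were EGR1 (-0.91), DUSP2 (-0.82), PLK3 (-0.63), SPRED1 (-0.62), JUNB (-0.60), DUSP5 (-0.59) and DUSP4 (-0.49). Cell cycle genes were GINS2 (-0.69), CDC25A (-0.59), MCM4 (-0.56), CCND2 (-0.47), HJURP (1.01), CKAP2 (0.94), NDC80 (0.89) and MKI67 (0.64). Sterol genes were ABCA1 (0.78), SREBF1 (0.46) and MYLIP (0.44), the last lost without either 2 h or either 6 h library (adjusted p 0.0661 to 0.221) and in DESeq2 (0.0731).

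Glycolysis genes were HK2 (-0.66), PFKFB3 (-0.65), LDHA (-0.39) and ENO1 (-0.29), and autophagy genes ULK1 (0.89), ATG2A (0.77), CTSB (0.66) and SQSTM1 (0.31). Heat shock genes were HSPA8 (-0.83), HSPD1 (-0.53), CCT3 (-0.39) and CCT5 (-0.47), which shares 30.8% of its exonic length with an antisense gene, so that its level is uncertain. NRF2 targets were ABCC4 (-0.74), ME1 (-0.66), TKT (-0.55) and TXNRD1 (-0.47). Ribosomal and respiratory genes were RPL24 (-0.31), RPL13 (-0.26), ATP5MC1 (-0.50), ATP5F1D (-0.41), CYC1 (-0.39) and ATP5PB (-0.32). Histone genes were H2BC15 (1.09), H2BC21 (1.05), H2AC6 (0.89) and H2AC11 (0.71), the last lost without 2 h replicate 1 (0.0782) or 6 h replicate 1 (0.13). Of the remaining genes PIM3 (-0.64), MAF (-0.27), WNK1 (0.35) and WNK2 (-1.01) differed under every alternative tried. Those of STK39 (0.28), OXSR1 (0.19) and XBP1 (-0.21) were lost without either 2 h or either 6 h library (0.0655 to 0.14, 0.155 to 0.323 and 0.0735 to 0.139). OXSR1 was also lost with the replicate block (0.0549) and no filter (0.0807), and XBP1 with library size alone (0.0886). The call of MYC (-0.21) was lost without 2 h replicate 1 (0.0508), 6 h replicate 1 (0.0569) or 6 h replicate 2 (0.064).

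Of 57 G2-M genes 32 were called lower than DMSO at 2 h and 0 higher, and 42 were called higher at 6 h than at 2 h and 0 lower, with list calls made at the preset correlation and lost with an estimated correlation (adjusted p = 0.0803 and 0.107). Removing the GC and length trend left both tests with the preset correlation past the threshold (larger adjusted p = 7.14e-19), which argues against that trend as the whole cause. A wrong scaling factor moves all genes alike, so it would not set the list apart from other genes. The list median minus that of all genes was -0.27 at 2 h (bootstrap interval over members -0.33 to -0.22) and 0.41 between the times (0.29 to 0.53). The list was flagged because camera had set it apart from other genes, so this distance restates that call and is no separate support. The interval treats members as independent and does not measure the spread between libraries. Time in culture cannot be told apart from treatment, since each treated time is 1 group and the labels leave open which time the DMSO libraries match (median difference 0.42). An effect of WNK463 stays open beside it.

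Of 427 zinc-finger genes 96 were called down and 30 up at 2 h (camera, adjusted p = 0.000323, and adjusted p = 0.0192 with an estimated correlation), and of 27 snoRNA host genes 13 down and 0 up at 2 h (4.1e-12, and adjusted p = 0.0327 with an estimated correlation), with 101 down and 55 up (0.149) and 14 down and 0 up (1.01e-08, and adjusted p = 0.0586 with an estimated correlation) at 6 h. Both families were chosen after ZNF587B, ZNF785 and SNHG4 were seen among the largest falls at 2 h, so these p-values are no independent support. They were adjusted over the families kept, not over all those looked at, and no library was left out in turn. After removal of the GC and length trend the zinc-finger median at 2 h was -0.19 and still past the threshold, which argues against that trend as the whole cause. A complete stop of RNA synthesis is argued against by immediate early genes, of which 22 rose and 2 fell of 38 (median 0.81, camera, adjusted p = 1.86e-22, and adjusted p = 0.0655 with an estimated correlation). That list was already known to be up when this test was chosen. A partial or selective loss of transcription is not addressed by it. A lower yield of nuclear RNA may be a source at 2 h, since 117 sense intronic transcripts had a median of -0.35 (adjusted p = 0.0264, adjusted p = 0.0717 with an estimated correlation, and 0.0525 after the GC and length correction). Of these transcripts 6 were called down and 0 up, against 1293 down and 1349 up of all 15548 genes. The share called down was thus not above that of all genes. At 6 h the sense intronic transcripts were not called as a set (median -0.25, 10 down and 2 up, adjusted p = 0.466) while the host genes were. Directly between the times neither set was called (camera, adjusted p = 0.277 for sense intronic transcripts and 0.19 for host genes). A lower yield of nuclear RNA stays open beside an effect of WNK463 on transcription, which was not tested.

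Of 24 replication-dependent histone genes 10 were called higher than DMSO at 6 h and 0 lower, with a list call made at the preset correlation and lost with an estimated correlation (adjusted p = 0.135). Removing the GC and length trend left the test with the preset correlation past its threshold (adjusted p = 0.000515), which argues against that trend as the whole cause. Carry-over of RNA without poly(A) tails is argued against only weakly by 5 small RNAs of at least 1 CPM, with a mean log2 change of -0.31 (SE 0.316) against a histone median of 0.92. They ranged from -1.29 (SNORA73B) to 0.67 (Y_RNA), and the SE is taken over unlike RNAs, not over libraries. That minimum was set after the values were seen and the test rests on 5 RNAs. A larger share of cells in S phase would raise G1-S genes, of which 22 fell and 8 rose of 55 (median -0.19, camera for a fall, adjusted p = 0.00456, and adjusted p = 0.121 with an estimated correlation), which runs against it, but with members called in both directions it cannot be told apart. An effect of WNK463 stays open beside it.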

How the results depend on the processing

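The GC and length correction and the split of the controls were chosen only after the results were seen. In 2 h with DMSO 1560 genes passed an adjusted p of 0.01, and 419, 953 and 316 genes in 2 h with DMSO, 6 h with DMSO and 6 h with 2 h passed with a log2 change of at least 1, as stricter thresholds give fewer. With a library left out the calls ranged from 1527 (without 2 h replicate 2) to 2911 (without DMSO replicate 2) in 2 h with DMSO, from 4021 (without 6 h replicate 1) to 5600 in 6 h with DMSO, and from 2288 (without 6 h replicate 1) to 4661 (without DMSO replicate 1) in 6 h with 2 h. The lone library of a group is there assumed to vary like the other groups, and fewer samples carry less weight. In 6 h with 2 h, a fit of only those groups, without any DMSO library, gave 4639 calls against 3772 in the reported fit. A rise in that comparison thus also came when DMSO was left out of the estimate of spread. The cause of the rises was not tested further. Under other scalings, filters and tests the calls were 1904 to 3353, 4595 to 6159 and 3069 to 4639, lowest with DESeq2 in each comparison, and in these alternatives no gene called in the reported results was called in the opposite direction. With the replicate block they were 2658, 5686 and 3807, and same-numbered libraries showed no shared deviation (correlations -0.005, -0.038 and -0.021). With an estimated correlation camera called 0, 1 and 1 lists (16, 12 and 9 at an unadjusted p under 0.05), and fry called 25, 27 and 23. The estimated setting also has fewer degrees of freedom, so the drop need not reflect correlation between genes alone. The cause was not tested. With a library left out the agreement of both times ranged from 0.437 (without 2 h replicate 2) to 0.76 (without DMSO replicate 1), while unchanged groups simulated for the same designs gave at most 0.398 and 0.71, respectively. Only without DMSO replicate 2 was the agreement (0.697) below that of the simulation (0.716 to 0.758). These simulations gave all groups the same spread, so they do not settle how much noise shared through the controls adds. The genes called at both times in the same direction ranged from 1110 (without 2 h replicate 2) to 2072 (without DMSO replicate 2), against 0 simulated, and the cause was not tested. Unchanged simulated groups have hardly any calls at either time, so a simulated 0 is no measure of this overlap. Under the other alternatives the genes called at both times in the same direction numbered 1306 (DESeq2) to 2305 (GC and length correction). With the controls split the agreement was 0.331 and 0.323, or 0.275 and 0.283 with the genes that pass the filter of the fewer libraries, and 0.549 and 0.523 over genes of at least 4 CPM. Each change then has a single control library of its own, so the noise of the controls is no longer shared. Of 263 results of named genes 245 kept their direction and their side of the threshold in all alternatives and 18 lost or gained a call. In simulated data a log2 change of 0.3 was recovered in 19.4% of genes of at least 4 CPM, so changes of that size were mostly missed in the simulation.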

Other observations

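The families in this part and their tests were chosen only after the results were seen. Nuclear long noncoding RNAs gave 6 down and 0 up of 7 at 2 h (median -0.80, adjusted p = 4.99e-23, and adjusted p = 0.0192 with an estimated correlation), among them MALAT1 (-1.32), MIAT (-0.66) and TUG1 (-0.47), and 5 down and 0 up at 6 h (median -0.55, adjusted p = 5.97e-05, and adjusted p = 0.0586 with an estimated correlation). Sense intronic transcripts had a median of -0.35 at 2 h, and a lower yield of nuclear RNA in the 2 h libraries was not excluded. Chemokine and interleukin genes gave 7 up and 1 down of 21 at 2 h (adjusted p = 9.36e-07, and adjusted p = 0.0327 with an estimated correlation) and 8 up and 3 down at 6 h (0.000295, and adjusted p = 0.0586 with an estimated correlation), including CCL2 (2.46 and 2.40) and IL10 (1.35 and 1.66). Mitochondrial ribosomal protein genes gave 47 down and 2 up of 77 at 6 h (1.01e-08, and adjusted p = 0.0586 with an estimated correlation). Cytosolic tRNA synthetase genes gave 12 down and 2 up of 17 at 6 h (0.000525, and adjusted p = 0.0586 with an estimated correlation). RAB GTPase genes gave 16 up and 5 down of 50 at 6 h (0.0181, and adjusted p = 0.0849 with an estimated correlation). Antisense transcripts (50 down and 18 up of 948 at 2 h, 0.116, but adjusted p = 0.0338 with an estimated correlation) and proteasome subunits (11 down and 0 up of 38 at 6 h, 0.128) were not called with the preset correlation.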
